A study of Mus musculus with 15 samples.

How the data were processed

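RNA was sequenced from MAP cells, an immortalized line of mouse adipocyte progenitors, in 15 libraries. Per the labels' protocols, confluent cells were differentiated for 2 days with insulin, isobutylmethylxanthine, dexamethasone and rosiglitazone. They then spent 2 days in insulin and rosiglitazone. At day 7 to 8 the differentiated cells received forskolin, which activates adenylyl cyclase and raises cAMP, or rosiglitazone, an agonist of the nuclear receptor PPARγ. The groups were vehicle, forskolin for 4 h (FSK4h), 1 day (FSK1D) or 3 days (FSK3D), and rosiglitazone for 3 days (Rosi3D), with 3 libraries each. The doses of these treatments and the time at which the vehicle cells were harvested are not given in the sources used here. Total RNA was extracted with TRIzol and depleted of ribosomal RNA before library preparation, per the labels' protocols.

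The authors' deposited table holds whole-number read counts per gene, not normalized, for 24421 gene symbols. Per the submitters' processing notes, the tools were fastp, STAR and featureCounts and the genome build was GRCm38 (mm10). Their versions, the gene annotation, the handling of read pairs and strand, and the handling of reads that match several genes are not given in the sources used here. Genes that overlap, such as Elovl3 and Pitx3, Ccnd1 and LTO1, Acaa1b and Dlec1, Prg4 and Tpr, Lrrc39 and Trmt13, or Mb and Apol6, and near-identical copies, such as Acta1 with Acta2 and Acaa1a with Acaa1b, are therefore uncertain. In each library low counts were mostly even. Between 407 and 539 genes had a count of 1 and between 721 and 907 a count of 2, while 49.2% to 51.3% of counts from 101 to 1000 were even. Counts of this kind arise when both mates of a read pair are counted. Intervals of ratios of low counts were therefore computed on counts divided by 2, while the tests used the counts as deposited. The table covers no mitochondrially encoded mRNA among the 13 looked for. Of the symbols, 23384 (95.8%) matched GENCODE vM21, from which the positions on GRCm38 were taken.

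The columns name a group and a running library number (S1 to S15) that is not the replicate number of the labels, so each column was used as an unnumbered library of its group. Nothing in the labels says that the libraries of a group came from separate cultures. The p-values then measure only the spread between these libraries, which may be technical. Library totals ran from 14056200 (FSK3D S11) to 56282582 (Rosi3D S13) counts. Within a group no pair of libraries differed by as little as sampling noise, with a chi-square per degree of freedom of 3.20 to 11.8. Pearson's r across genes was 0.987 to 0.993 on log2 CPM (counts scaled to a common library size), with genes not being independent replicates. No library was dropped.

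Genes were filtered with filterByExpr, which left 14421, and 4584 genes had no read in any library. Library sizes were scaled with the trimmed mean of M values (TMM). Differences were tested in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16 (robust fit, 1 mean per group, all 15 libraries, 10 residual degrees of freedom) and two-sided p-values with Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05, and calls of at least 2-fold were counted too. The standard error (SE) of a log2 fold change was its size divided by the square root of the F statistic. The common biological coefficient of variation was 5.97%. Expression is given as TMM-scaled CPM, mean ± standard deviation (SD) of 3 libraries. A ratio of low counts, where given, has an exact binomial 95% interval. Other genes with few counts in a group are given only as log2 fold changes with SE. Among them are Il6 (19 counts over the vehicle libraries), Fga (13), Fgf21 (24) and Tnfrsf9 (18). A group at 0 was set to a floor of 3 halved counts over the group. Such intervals and floors cover counting error only.

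The tested comparisons were each treatment against vehicle, FSK3D against Rosi3D, the 3 pairs of forskolin times, and any change over vehicle and the 3 forskolin times. A gene called in 1 direction at all 3 times was counted as sustained. One called at 4 h whose difference between FSK3D and FSK4h was called in the other direction was counted as early. One called at 3 days whose difference between FSK3D and FSK4h was called in the same direction was counted as late, so that a gene can be in more than 1 class.

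Lists of genes fixed before the data were examined numbered 32, of which 30 had at least 5 tested members. They covered thermogenic, beige, white, mature adipocyte and progenitor genes, cAMP-CREB and PPAR targets, lipogenesis, lipolysis, fatty acid oxidation, nuclear oxidative phosphorylation, mitochondrially encoded mRNAs, the TCA cycle, creatine and calcium cycling, extracellular matrix, myofibroblast genes, inflammatory, interferon, unfolded protein, cell cycle, circadian, cholesterol, glycolysis and hypoxia genes, secreted factors, chromatin enzymes, ribosomal proteins, abundant noncoding RNAs, and markers of macrophages, endothelium, skeletal muscle and nerve or glia. Lists share members where a gene has several roles. They were tested with camera of limma 3.58.1, which compares a list with the other genes, on log2 CPM with a prior count of 2 and a preset correlation of 0.01. Camera with an estimated correlation and fry, whose p tests whether a list's genes move 1 way on balance, were alternatives. Named genes follow a rule that was also fixed then. They are 20 fixed adipocyte genes, the 6 called genes with the largest rise and the 6 with the largest fall per comparison among genes with an average log2 CPM of at least 1 whose libraries did not overlap between the groups, leaving out predicted and unnamed genes, and per list up to 2 risen and 2 fallen members with the smallest p. Some genes that this rule names are not reported here. A gap between all 3 libraries of both groups arises by chance for 10% of unchanged genes.

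Alternatives chosen before the data were examined were DESeq2 1.42.0, its size factors (RLE) in edgeR, library size alone, every gene with a read, at least 1 CPM in 3 libraries, the 20 most abundant genes left out, only the groups compared, an adjusted p under 0.01, and each library left out. Halved counts and libraries thinned to the smallest total were added after the data were seen. Overlap of calls against the shared vehicle libraries was set beside 100 simulations without effects. The steps were tested on simulated counts in which 200 of 14421 genes changed in each group, as many up as down. Counts were drawn with the dispersions fitted to the data. The results do not show how the scaling and the tests perform when far more genes change, as in these data. At 4-fold, 62 of 66 changed genes were recovered in FSK4h, 62 in FSK1D, 62 in FSK3D and 65 in Rosi3D. At 2-fold the numbers were 58, 56, 51 and 56 of 67, and at 1.5-fold 46, 48, 44 and 47 of 67. Of 14221 unchanged genes, 15, 12, 5 and 13 were called. For the time course, 496 of 586 changed genes were recovered and 24 unchanged genes were called. Figures were drawn with matplotlib 3.10.9.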

Results

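The data comprised counts for 15 libraries of differentiated MAP adipocytes. Vehicle cells were set against cells given forskolin for 4 h, 1 day or 3 days and against cells given rosiglitazone for 3 days, treatments that the labels describe as inducing browning of the adipocytes. Browning is the gain of heat-producing, mitochondria-rich features by fat cells. Total counts were 26388586 to 31089519 in vehicle, 27514310 to 39968932 in FSK4h, 25638062 to 26945435 in FSK1D, 14056200 to 31079564 in FSK3D and 20984580 to 56282582 in Rosi3D, with 3 libraries in each group. Fold changes are log2 ± SE throughout, and levels are CPM ± SD with n = 3. All 5 groups formed separate clusters on principal components of the tested genes, of which the first held 44.4% and the second 16.4% of the variance.

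The precursor of ribosomal RNA, Rn45s, took the most counts of any gene, and its share moved with the groups. It was 8.53% ± 0.0385 (SD, n = 3) in vehicle, 8.68% ± 0.175 in FSK4h, 7.60% ± 0.564 in FSK1D, 4.77% ± 0.890 in FSK3D and 6.63% ± 0.534 in Rosi3D. Within FSK3D it ran from 4.15% to 5.79%. Because the libraries were depleted of ribosomal RNA, this share cannot stand for the amount that the cells made. TMM factors averaged 0.907 in FSK4h and 1.02 to 1.04 in the other groups. With library size alone, the median of all genes shifted by -0.19 in FSK4h against vehicle, by 0.16 in FSK1D against FSK4h and by 0.18 in FSK3D against FSK4h. Changes are reported relative to the TMM-scaled level. Camera with its preset correlation also called up to 17 of 30 lists in other splits of the same libraries. Those splits mix both groups unevenly and keep part of their real difference, so they do not show what chance alone would call. Each list is given with the counts of its members and with the p of an estimated correlation. With that correlation, the calls that held were the cAMP-CREB targets in FSK4h, in FSK1D and in FSK3D against FSK4h, and the myofibroblast genes in FSK1D.

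After 4 h of forskolin Ucp1 and most cAMP-responsive, hypoxia and stress-response genes were higher than in vehicle, and 14 of 24 interferon-stimulated genes were lower. With an estimated correlation camera called the cAMP-CREB list alone, with adjusted p = 0.176 for hypoxia, 0.168 for the stress response and 0.817 for interferon-stimulated genes. Against vehicle 4093 genes were higher and 4421 lower, 784 and 909 of them by at least 2-fold. The largest rise under the rule for named genes was in Nppc (chromosome 1, 86666291 to 86670571, minus strand), which encodes the precursor of C-type natriuretic peptide. Its level was 13.3 ± 1.17 CPM against 0.0245 ± 0.0424 in vehicle (8.96 ± 0.50, adjusted p = 1.04e-14). With 2 counts over the vehicle libraries, the ratio of 597 has a counting interval of 107 to 23594.5. Ucp1 (chromosome 8, 83290352 to 83298452, plus strand), the uncoupling protein of brown fat mitochondria, was at 8.42 ± 0.648 CPM against 0.0753 ± 0.0829 (6.68 ± 0.35, adjusted p = 8.70e-18), a ratio of 109 with a counting interval of 36.8 to 351.

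Among cAMP-CREB targets, 29 rose and 2 fell of 32 tested genes (29 and 2 adjusted over the list alone), with a median of 2.08 and camera adjusted p = 4.65e-16 (adjusted p = 0.00450 with an estimated correlation). The orphan nuclear receptors Nr4a3 and Nr4a1 (chromosome 15, 101254269 to 101274795, plus strand) rose by 7.63 ± 0.19 and 3.69 ± 0.088, the kinase Sik1 by 3.25 ± 0.069 and the phosphodiesterase Pde4d by 2.19 ± 0.051. Pde4a (-0.66 ± 0.079) and Pde7b (-1.047 ± 0.18) fell. Ppargc1a (chromosome 5, 51454250 to 51567726, minus strand), a coactivator of mitochondrial genes, rose by 1.22 ± 0.078. The thermogenic list as a whole had no 1 direction, as 7 rose and 5 fell of 20 tested genes (7 and 6 adjusted over the list alone), with camera adjusted p = 0.720 (adjusted p = 0.913 with an estimated correlation). Its members Adrb3, the beta-3 adrenergic receptor, and Ebf2 fell by 2.10 and 0.63 on the log2 scale.

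Hypoxia targets were higher, with 15 higher and 0 lower of 17 tested members (15 and 0 adjusted over the list alone). They had a median of 1.495, camera adjusted p = 3.12e-10 (adjusted p = 0.176 with an estimated correlation). Vegfa, an angiogenic growth factor, rose by 2.06 ± 0.053 and the glucose transporter Slc2a1 by 2.81 ± 0.064. In the glycolysis list, which also holds Slc2a1, 16 rose and 3 fell of 22 tested genes (16 and 4 adjusted over the list alone), with camera adjusted p = 3.32e-06 (adjusted p = 0.567 with an estimated correlation). Slc2a4, the insulin-responsive transporter, fell (-1.31 ± 0.15), while Pdk4 rose (1.64 ± 0.057). Of the unfolded protein and stress response, 22 rose and 0 fell of 26 tested genes (23 and 0 adjusted over the list alone), with camera adjusted p = 1.16e-08 (adjusted p = 0.168 with an estimated correlation). The chaperone Hspa5 rose by 1.34 ± 0.041 and Dnajb9 by 1.42 ± 0.052.

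In the inflammatory list 13 rose and 2 fell of 21 tested genes (13 and 2 adjusted over the list alone), with camera adjusted p = 0.00511 (adjusted p = 0.567 with an estimated correlation). The cytokines Il6 (chromosome 5, 30013114 to 30019981, plus strand) and Lif rose by 6.90 ± 0.25 and 4.31 ± 0.13, and the chemokine Cxcl12 fell (-1.27 ± 0.077). Interferon-stimulated genes fell, with 0 higher and 14 lower of 24 tested members (0 and 15 adjusted over the list alone). They had camera adjusted p = 0.00606 (adjusted p = 0.817 with an estimated correlation), and 0.100 with library size alone. Ifit2 stood at 18.0 ± 2.02 CPM against 83.1 ± 8.98 in vehicle (-2.20 ± 0.17).

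Lipid genes moved both ways at 4 h. Among PPAR targets 16 rose and 5 fell of 26 tested genes (16 and 6 adjusted over the list alone), with camera adjusted p = 0.00132 (adjusted p = 0.667 with an estimated correlation). The lipid droplet protein Plin2 rose by 2.31 ± 0.051, the triglyceride synthesis enzyme Dgat1 by 1.89 ± 0.049 and the secreted lipase inhibitor Angptl4 by 1.61 ± 0.059. In the lipogenesis list 4 rose and 14 fell of 24 tested genes (4 and 14 adjusted over the list alone), with camera adjusted p = 0.0572 (adjusted p = 0.817 with an estimated correlation). Without vehicle S1 or FSK4h S5 the list was called (0.0161 and 0.0353), as with library size alone (0.0299) and in thinned libraries (0.0441). Fatty acid synthase, Fasn, fell (-1.09 ± 0.072, adjusted p = 1.52e-10). Fgf21 (chromosome 7, 45613886 to 45615490, minus strand), a metabolic hormone, rose by 4.22 ± 0.32. Leptin (Lep, chromosome 6, 29060220 to 29073877, plus strand) had no count in any FSK4h or FSK1D library against 44 in vehicle, at least 7.23-fold and 6.51-fold lower with halved counts and a floor of 3 over the group. Large falls were also seen in Rspo2, an enhancer of Wnt signalling (-4.56 ± 0.19), the apoptosis regulator Bmf (-4.03 ± 0.12), Wnt16 (-3.62 ± 0.27) and the iron exporter Slc40a1 (-3.61 ± 0.15). Tll1, a metalloprotease, rose by 5.07 ± 0.098 and the fibrinogen chain Fga by 5.30 ± 0.32.

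Small shifts at 4 h depended on the scaling. Ribosomal proteins had 28 higher and 0 lower of 39 tested members (29 and 0 adjusted over the list alone), with a median of 0.18 and camera adjusted p = 2.38e-04 (adjusted p = 0.667 with an estimated correlation). With library size alone 2 rose and 1 fell, with a median of -0.01 and adjusted p = 0.0668. Nuclear oxidative phosphorylation genes had 18 higher and 3 lower of 75 tested members (13 and 1 adjusted over the list alone), with camera adjusted p = 0.123 (adjusted p = 0.913 with an estimated correlation), but 4 rose and 28 fell with library size alone. With that scaling 2519 genes were called higher and 6708 lower, so that higher genes made up 27.3% of calls in place of 48.1%.

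After 1 day of forskolin most cAMP-responsive, cell cycle and glycolysis genes were higher than in vehicle, and most smooth muscle and cholesterol synthesis genes were lower. With an estimated correlation camera called the cAMP-CREB and myofibroblast lists alone, with adjusted p = 0.0975 for cholesterol synthesis, 0.332 for the cell cycle and 0.145 for glycolysis. Against vehicle 2805 genes were higher and 2986 lower, 542 and 511 of them by at least 2-fold. Lcn2 (chromosome 2, 32384633 to 32388252, minus strand), an iron-siderophore binding protein secreted in inflammation, reached 63.0 ± 3.47 CPM against 0.318 ± 0.236 in vehicle (7.64 ± 0.25, adjusted p = 5.40e-15). Acta2 (chromosome 19, 34241090 to 34255590, minus strand), smooth muscle actin, fell from 214 ± 4.44 to 16.1 ± 1.053 CPM (-3.74 ± 0.062, adjusted p = 3.09e-31). Ucp1 was at 1.15 ± 0.0834 CPM (3.82 ± 0.47, adjusted p = 2.62e-08).

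Of cAMP-CREB targets, 28 rose and 1 fell of 32 tested genes (28 and 1 adjusted over the list alone), with a median of 1.052 and camera adjusted p = 6.62e-15 (adjusted p = 0.00605 with an estimated correlation). Nr4a2 rose by 4.01 ± 0.11, Nr4a1 by 2.87 ± 0.088 and Junb by 1.89 ± 0.075, while Egr1 fell (-1.002 ± 0.087). Among myofibroblast and smooth muscle genes 1 rose and 11 fell of 14 tested genes (1 and 11 adjusted over the list alone), with a median of -1.09 and camera adjusted p = 2.23e-06 (adjusted p = 0.0186 with an estimated correlation). Tagln, an actin-binding protein, fell with Acta2 (-3.25 ± 0.11) and Cald1 rose (0.23 ± 0.056). Hypoxia targets had 16 higher and 1 lower of 17 tested members (16 and 1 adjusted over the list alone), with camera adjusted p = 2.88e-14 (adjusted p = 0.0743 with an estimated correlation), and the collagen hydroxylases P4ha1 and P4ha2 rose by 1.32 ± 0.045 and 1.57 ± 0.058. In glycolysis 16 rose and 3 fell of 22 tested genes (17 and 3 adjusted over the list alone), with camera adjusted p = 8.70e-11 (adjusted p = 0.145 with an estimated correlation). Pgk1 rose by 1.80 ± 0.052 and Gapdh by 1.76 ± 0.053.

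Cholesterol synthesis genes had 0 higher and 21 lower of 24 tested members (0 and 21 adjusted over the list alone), a median of -0.88 and camera adjusted p = 6.83e-15 (adjusted p = 0.0975 with an estimated correlation). Sc5d fell by 1.24 ± 0.060 and Nsdhl by 1.21 ± 0.064 on the log2 scale. In lipogenesis 4 rose and 18 fell of 24 tested genes (4 and 19 adjusted over the list alone), with camera adjusted p = 3.56e-06 (adjusted p = 0.410 with an estimated correlation). Fasn stayed below vehicle (-1.28 ± 0.072) and Elovl6 fell (-0.95 ± 0.062), while the desaturase Scd1 rose (0.52 ± 0.051). Adiponectin (Adipoq, chromosome 16, 23146536 to 23158028, plus strand), a hormone of mature adipocytes, was at 693 ± 38.4 CPM against 1528 ± 90.0 (-1.14 ± 0.047, adjusted p = 2.20e-20). Mature adipocyte genes as a list moved both ways, with 5 higher and 9 lower of 20 tested members (5 and 9 adjusted over the list alone) and camera adjusted p = 0.134 (adjusted p = 0.801 with an estimated correlation), although the list was called without vehicle S1 (0.0395) or FSK1D S8 (0.0323). So did thermogenic genes, of which 7 rose and 7 fell of 20 tested (7 and 8 adjusted over the list alone), with camera adjusted p = 0.688 (adjusted p = 0.851 with an estimated correlation). Their median was below 0 (-0.13) and their mean above it (0.096). Ppargc1a was below vehicle (-0.79 ± 0.086), as were Adrb3 (-2.32 ± 0.071) and Ppara (-1.35 ± 0.089).

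Cell cycle genes had 22 higher and 0 lower of 30 tested members (22 and 0 adjusted over the list alone), a median of 0.30 and camera adjusted p = 1.51e-07 (adjusted p = 0.332 with an estimated correlation). Top2a rose by 0.49 ± 0.043 and Ccne1 by 0.92 ± 0.083. The unfolded protein list had 18 higher and 1 lower of 26 tested members (18 and 1 adjusted over the list alone), with camera adjusted p = 2.31e-06 (adjusted p = 0.145 with an estimated correlation), and Xbp1 rose by 0.94 ± 0.047. In the inflammatory list 12 rose and 6 fell of 21 tested genes (13 and 6 adjusted over the list alone), with camera adjusted p = 0.0396 (adjusted p = 0.497 with an estimated correlation). Its preset call was lost without vehicle S2 (0.0846), FSK1D S7 (0.0735) or FSK1D S9 (0.0544). It was also lost under RLE factors (0.0630), a 1 CPM filter (0.0870), halved counts (0.0754) and thinning (0.0967). Il6 remained high (5.88 ± 0.27), Saa3 rose (4.37 ± 0.28) and Vcam1 fell (-1.24 ± 0.055). Prg4, the joint lubricant proteoglycan, rose by 6.33 ± 0.13 and Tnfrsf9 (chromosome 4, 150914562 to 150946102, plus strand), a costimulatory receptor used as a beige marker, by 5.88 ± 0.26. The nerve growth factor receptor Ngfr (-4.66 ± 0.20) and the PACAP receptor Adcyap1r1 (-3.40 ± 0.17) fell.

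After 3 days of forskolin, most thermogenic, mitochondrial and mature adipocyte genes were higher and 28 of 30 cell cycle genes lower than in vehicle. These lists were called with the preset correlation and not with an estimated one, with adjusted p = 0.156 for thermogenic, 0.156 for oxidative phosphorylation, 0.298 for mature adipocyte and 0.156 for cell cycle genes. There were 3740 genes higher and 3888 lower, 632 and 555 of them by at least 2-fold. Ucp1 was at 5.25 ± 0.939 CPM against 0.0753 ± 0.0829 (5.99 ± 0.37, adjusted p = 2.29e-15), a ratio of 66.2 with a counting interval of 22.3 to 216. In these libraries the Rn45s share was 4.77% against 8.53% in vehicle.

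Of thermogenic genes, 14 rose and 1 fell of 20 tested members (14 and 1 adjusted over the list alone), with a median of 0.87 and camera adjusted p = 4.00e-05 (adjusted p = 0.156 with an estimated correlation). The lipid droplet protein Cidea (chromosome 18, 67343604 to 67367785, plus strand) rose by 1.59 ± 0.21, the fatty acid elongase Elovl3 by 3.58 ± 0.29, the secreted factor Nrg4 by 2.00 ± 0.10, and the muscle and brown fat isoforms of cytochrome c oxidase Cox7a1 and Cox8b by 2.24 ± 0.18 and 1.74 ± 0.16. Ppargc1a was above vehicle again (0.64 ± 0.081), and Adrb3 remained below (-0.89 ± 0.066). Fatty acid oxidation had 22 higher and 0 lower of 24 tested members (22 and 0 adjusted over the list alone), with camera adjusted p = 1.16e-11 (adjusted p = 0.156 with an estimated correlation), and Decr1 rose by 1.28 ± 0.057. Among nuclear genes of oxidative phosphorylation 66 rose and 1 fell of 75 tested members (68 and 1 adjusted over the list alone), with a median of 0.43 and camera adjusted p = 1.04e-14 (adjusted p = 0.156 with an estimated correlation). Cytochrome c (Cycs) rose by 1.18 ± 0.062 and Uqcrc2 by 0.73 ± 0.057. All tested TCA cycle genes rose, with 20 higher and 0 lower of 20 tested members (20 and 0 adjusted over the list alone) and camera adjusted p = 1.49e-10 (adjusted p = 0.156 with an estimated correlation), among them Idh3a (1.19 ± 0.056) and Pdhb (0.93 ± 0.058).

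Mature adipocyte genes had 17 higher and 2 lower of 20 tested members (17 and 2 adjusted over the list alone), with camera adjusted p = 2.88e-06 (adjusted p = 0.298 with an estimated correlation). Lipoprotein lipase, Lpl, rose by 0.83 ± 0.054, Fabp4 by 0.59 ± 0.12, resistin (Retn) by 0.88 ± 0.077, Pparg by 0.58 ± 0.071 and Adipoq by 0.22 ± 0.046. PPAR targets had 21 higher and 1 lower of 26 tested members (21 and 1 adjusted over the list alone), with camera adjusted p = 1.91e-08 (adjusted p = 0.156 with an estimated correlation). Acaa1b and Pck1 rose by 3.01 ± 0.075 and 1.75 ± 0.075, and Angptl4 fell (-0.53 ± 0.060). The lipogenesis list had 17 higher and 4 lower of 24 tested members (18 and 4 adjusted over the list alone), with camera adjusted p = 9.59e-05 (adjusted p = 0.309 with an estimated correlation). Scd1 rose by 0.80 ± 0.052, and Fasn, at 5017 ± 651 CPM, was not called different from vehicle (0.05 ± 0.071, adjusted p = 0.608). For lipolysis and beta-adrenergic signalling 12 rose and 3 fell of 21 tested members (12 and 3 adjusted over the list alone), with camera adjusted p = 0.00326 (adjusted p = 0.268 with an estimated correlation). Glycolysis had 19 higher and 1 lower of 22 tested members (19 and 1 adjusted over the list alone), with camera adjusted p = 2.83e-11 (adjusted p = 0.156 with an estimated correlation), and hypoxia targets 13 higher and 1 lower of 17 tested members (14 and 1 adjusted over the list alone), with camera adjusted p = 1.34e-07 (adjusted p = 0.156 with an estimated correlation). Pdk1 rose by 2.08 ± 0.062. Of cAMP-CREB targets 18 higher and 5 lower of 32 tested members (18 and 5 adjusted over the list alone), with camera adjusted p = 0.00720 (adjusted p = 0.156 with an estimated correlation), and Nr4a1 was at 1.10 ± 0.094.

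Cell cycle genes fell, with 0 higher and 28 lower of 30 tested members (0 and 29 adjusted over the list alone), a median of -0.83 and camera adjusted p = 1.04e-14 (adjusted p = 0.156 with an estimated correlation). The replication factor Mcm5 fell (-1.09 ± 0.052), as did cyclin D1, Ccnd1 (-2.70 ± 0.10), whose exons overlap those of a neighbour. Cholesterol synthesis had 2 higher and 19 lower of 24 tested members (2 and 19 adjusted over the list alone), with camera adjusted p = 1.08e-07 (adjusted p = 0.156 with an estimated correlation). Ribosomal proteins had 0 higher and 30 lower of 39 tested members (0 and 33 adjusted over the list alone). They had a median of -0.33 and camera adjusted p = 1.04e-08 (adjusted p = 0.169 with an estimated correlation). Any relation to the Rn45s share was not tested. Myofibroblast genes had 1 higher and 11 lower of 14 tested members (1 and 11 adjusted over the list alone), with camera adjusted p = 2.31e-05 (adjusted p = 0.0854 with an estimated correlation). Acta2 was at 48.2 ± 3.11 CPM (-2.16 ± 0.056), and the intermediate filament Des rose (1.85 ± 0.16). Markers of adipocyte progenitors moved apart, with 4 higher and 8 lower of 18 tested members (4 and 8 adjusted over the list alone) and camera adjusted p = 0.219 (adjusted p = 0.537 with an estimated correlation). Pdgfrb fell (-0.72 ± 0.056), while Pdgfra (0.34 ± 0.043) and Zfp423 (0.63 ± 0.069) rose. The unfolded protein list had 15 higher and 7 lower of 26 tested members (15 and 7 adjusted over the list alone), with camera adjusted p = 0.0109 (adjusted p = 0.305 with an estimated correlation). Among genes with the largest changes, Tnfrsf9 rose by 5.09 ± 0.28, the mitochondrial carrier Slc25a34 by 4.31 ± 0.18 and Lcn2 by 4.21 ± 0.32. Gpr176, an orphan receptor, fell by 4.01 ± 0.18 and Cd300lb by 3.75 ± 0.33 on the log2 scale.

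**Figure D1:**
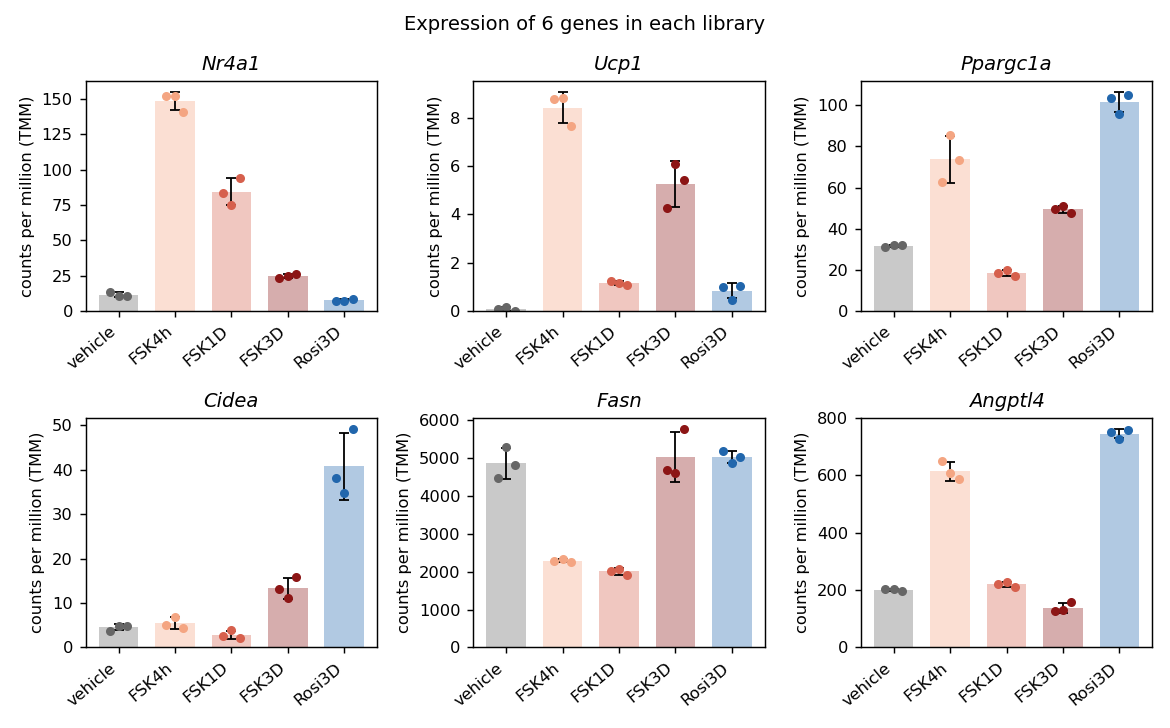
Expression of Nr4a1, Ucp1, Ppargc1a, Cidea, Fasn and Angptl4 in TMM-scaled CPM on linear axes, by group. Points are libraries, bars are means and error bars are SD (n = 3), and Ucp1 averaged 8.42 in FSK4h, 1.15 in FSK1D, 5.25 in FSK3D and 0.827 in Rosi3D.

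The time course asked which genes changed early, late or throughout. The harvest time of the vehicle cells, and whether time in culture differed between groups, are not given. Changes of each treatment against vehicle, including Rosi3D, in these classes and between forskolin times therefore cannot be told apart from time in culture. Only FSK3D and Rosi3D share a stated length of treatment. Over vehicle and the 3 forskolin times 11754 of 14421 genes changed. Sustained genes numbered 894 higher and 853 lower, of which 135 and 97 changed by at least 2-fold at each time. Early genes numbered 3067 higher and 3145 lower, and late genes 2536 higher and 2706 lower. With library size alone the counts were 661 and 1201 sustained, 1818 and 4895 early, and 2823 and 2231 late. Between FSK1D and FSK4h 4096 genes were higher and 4164 lower at 1 day, and with library size alone 2709 were lower and the share of higher calls was 68.8% in place of 49.6%. From 1 to 3 days 3639 were higher and 3719 lower, and from 4 h to 3 days 5045 and 4836, with a share of higher calls of 65.1% in place of 51.1% with library size alone.

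The cAMP-CREB targets were lower at 3 days than at 4 h. At 3 days against 4 h they had 2 higher and 29 lower of 32 tested members (2 and 29 adjusted over the list alone), with a median of -1.70 and camera adjusted p = 1.13e-10 (adjusted p = 0.0214 with an estimated correlation). At 1 day against 4 h they had 5 higher and 27 lower of 32 tested members (5 and 27 adjusted over the list alone), with camera adjusted p = 6.42e-08 (adjusted p = 0.0679 with an estimated correlation). From 4 h to 1 day there were 0 higher and 23 lower of 24 tested cholesterol genes (0 and 23 adjusted over the list alone), with camera adjusted p = 9.59e-12 (adjusted p = 0.222 with an estimated correlation). From 1 to 3 days thermogenic genes had 16 higher and 0 lower of 20 tested members (16 and 0 adjusted over the list alone), a median of 1.36 and camera adjusted p = 1.58e-06 (adjusted p = 0.252 with an estimated correlation). Oxidative phosphorylation genes had 69 higher and 0 lower of 75 tested members (69 and 1 adjusted over the list alone) over the same interval, with camera adjusted p = 1.94e-15 (adjusted p = 0.252 with an estimated correlation). Mature adipocyte genes had 18 higher and 0 lower of 20 tested members (18 and 0 adjusted over the list alone), with camera adjusted p = 2.90e-10 (adjusted p = 0.270 with an estimated correlation), and cell cycle genes 0 higher and 30 lower of 30 tested members (0 and 30 adjusted over the list alone), with camera adjusted p = 7.43e-21 (adjusted p = 0.115 with an estimated correlation).

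After 3 days of rosiglitazone, all 26 PPAR targets and most mitochondrial and thermogenic genes were higher than in vehicle, while all 30 cell cycle genes, 14 of 18 progenitor markers and 20 of 32 matrix genes were lower. These lists were called with the preset correlation and not with an estimated one, with adjusted p = 0.109 for PPAR targets, 0.109 for oxidative phosphorylation, 0.109 for thermogenic, 0.109 for cell cycle, 0.183 for progenitor and 0.283 for matrix genes. Against vehicle 4123 genes were higher and 4617 lower, 951 and 1148 of them by at least 2-fold. The largest rise under the rule for named genes was in Chrna2 (chromosome 14, 66135039 to 66152948, plus strand), a nicotinic acetylcholine receptor subunit, at 25.6 ± 1.52 CPM against 0.493 ± 0.216 (5.67 ± 0.20, adjusted p = 4.50e-22). Elovl3 (chromosome 19, 46131897 to 46135694, plus strand), which overlaps Pitx3, reached 9.83 ± 1.98 CPM against 0.308 ± 0.118 (4.96 ± 0.26, adjusted p = 9.81e-18). The matrix protein gene Mgp (chromosome 6, 136872435 to 136875823, minus strand) fell from 59.5 ± 4.03 to 1.80 ± 0.660 CPM (-5.12 ± 0.14, adjusted p = 1.84e-19). Ucp1 was at 0.827 ± 0.313 CPM (3.42 ± 0.48), a ratio of 11.51 with a counting interval of 3.64 to 38.1.

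Every tested PPAR target was called higher by edgeR, with 26 higher and 0 lower of 26 tested members (26 and 0 adjusted over the list alone), a median of 2.02 and camera adjusted p = 6.42e-17 (adjusted p = 0.109 with an estimated correlation). Fabp4 rose by 2.16 ± 0.12, Angptl4 by 1.89 ± 0.060 and Pdk4 by 2.19 ± 0.058, while Pparg itself was not called (-0.06 ± 0.071, adjusted p = 0.487). Fatty acid oxidation had 24 higher and 0 lower of 24 tested members (24 and 0 adjusted over the list alone), with camera adjusted p = 1.53e-16 (adjusted p = 0.122 with an estimated correlation). Nuclear oxidative phosphorylation had 74 higher and 0 lower of 75 tested members (75 and 0 adjusted over the list alone), a median of 1.02 and camera adjusted p = 4.91e-27 (adjusted p = 0.109 with an estimated correlation), and Cycs rose by 2.10 ± 0.061. In the TCA cycle 19 rose and 0 fell of 20 tested members (20 and 0 adjusted over the list alone), with camera adjusted p = 3.25e-13 (adjusted p = 0.183 with an estimated correlation). Thermogenic genes had 17 higher and 0 lower of 20 tested members (17 and 0 adjusted over the list alone), a median of 1.97 and camera adjusted p = 2.53e-08 (adjusted p = 0.109 with an estimated correlation). Cidea rose by 3.17 ± 0.20, Ppara by 2.72 ± 0.075, Cox8b by 2.36 ± 0.15 and Ppargc1a by 1.69 ± 0.078. Fgf21 rose by 4.06 ± 0.33.

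Mature adipocyte genes had 16 higher and 1 lower of 20 tested members (16 and 1 adjusted over the list alone), with camera adjusted p = 3.05e-07 (adjusted p = 0.283 with an estimated correlation). Plin4 rose by 1.12 ± 0.045 and complement factor D, Cfd, fell (-1.19 ± 0.075). Lipogenesis had 19 higher and 1 lower of 24 tested members (19 and 1 adjusted over the list alone), with camera adjusted p = 1.20e-06 (adjusted p = 0.283 with an estimated correlation), and Agpat2 rose by 2.26 ± 0.060. Lipolysis genes had 15 higher and 3 lower of 21 tested members (15 and 3 adjusted over the list alone), with camera adjusted p = 3.09e-05 (adjusted p = 0.183 with an estimated correlation). Glycolysis had 17 higher and 2 lower of 22 tested members (17 and 2 adjusted over the list alone), with camera adjusted p = 7.21e-07 (adjusted p = 0.237 with an estimated correlation), and the unfolded protein list 17 higher and 6 lower of 26 tested members (17 and 6 adjusted over the list alone), with camera adjusted p = 0.00987 (adjusted p = 0.301 with an estimated correlation). Cholesterol genes moved both ways, with 12 higher and 9 lower of 24 tested members (12 and 9 adjusted over the list alone) and camera adjusted p = 0.242 (adjusted p = 0.732 with an estimated correlation), and Insig1 rose by 1.62 ± 0.052.

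All tested cell cycle genes were lower in Rosi3D than in vehicle, with 0 higher and 30 lower of 30 tested members (0 and 30 adjusted over the list alone), a median of -1.09 and camera adjusted p = 1.91e-16 (adjusted p = 0.109 with an estimated correlation). Mki67 fell by 1.39 ± 0.048 and Top2a by 1.34 ± 0.045 on the log2 scale. Progenitor markers had 1 higher and 14 lower of 18 tested members (1 and 14 adjusted over the list alone), with camera adjusted p = 7.13e-04 (adjusted p = 0.183 with an estimated correlation), and Pdgfrb fell (-1.23 ± 0.056). For the extracellular matrix 8 rose and 20 fell of 32 tested members (8 and 20 adjusted over the list alone), with camera adjusted p = 0.00448 (adjusted p = 0.283 with an estimated correlation). Fibronectin, Fn1, fell (-1.80 ± 0.055) and Col3a1 rose (1.01 ± 0.054). Myofibroblast genes had 1 higher and 11 lower of 14 tested members (1 and 12 adjusted over the list alone), with camera adjusted p = 7.36e-05 (adjusted p = 0.109 with an estimated correlation), and Acta2 was at -2.51 ± 0.056. In the inflammatory list 1 higher and 10 lower of 21 tested members (1 and 9 adjusted over the list alone), with camera adjusted p = 0.0109 (adjusted p = 0.283 with an estimated correlation), and Csf1 fell (-1.63 ± 0.049). The receptor of interleukin 33, Il1rl1, fell by 3.63 ± 0.088, and Ctgf by 3.43 ± 0.14 on the log2 scale. Ribosomal proteins had 0 higher and 27 lower of 39 tested members (0 and 27 adjusted over the list alone), with camera adjusted p = 3.09e-05 (adjusted p = 0.301 with an estimated correlation), in libraries whose Rn45s share was 6.63%. Any relation to that share was not tested. Targets of cAMP-CREB had 5 higher and 20 lower of 32 tested members (5 and 20 adjusted over the list alone), with camera adjusted p = 0.0115 (adjusted p = 0.243 with an estimated correlation), and Nr4a1 fell (-0.61 ± 0.10).

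**Figure D2:**
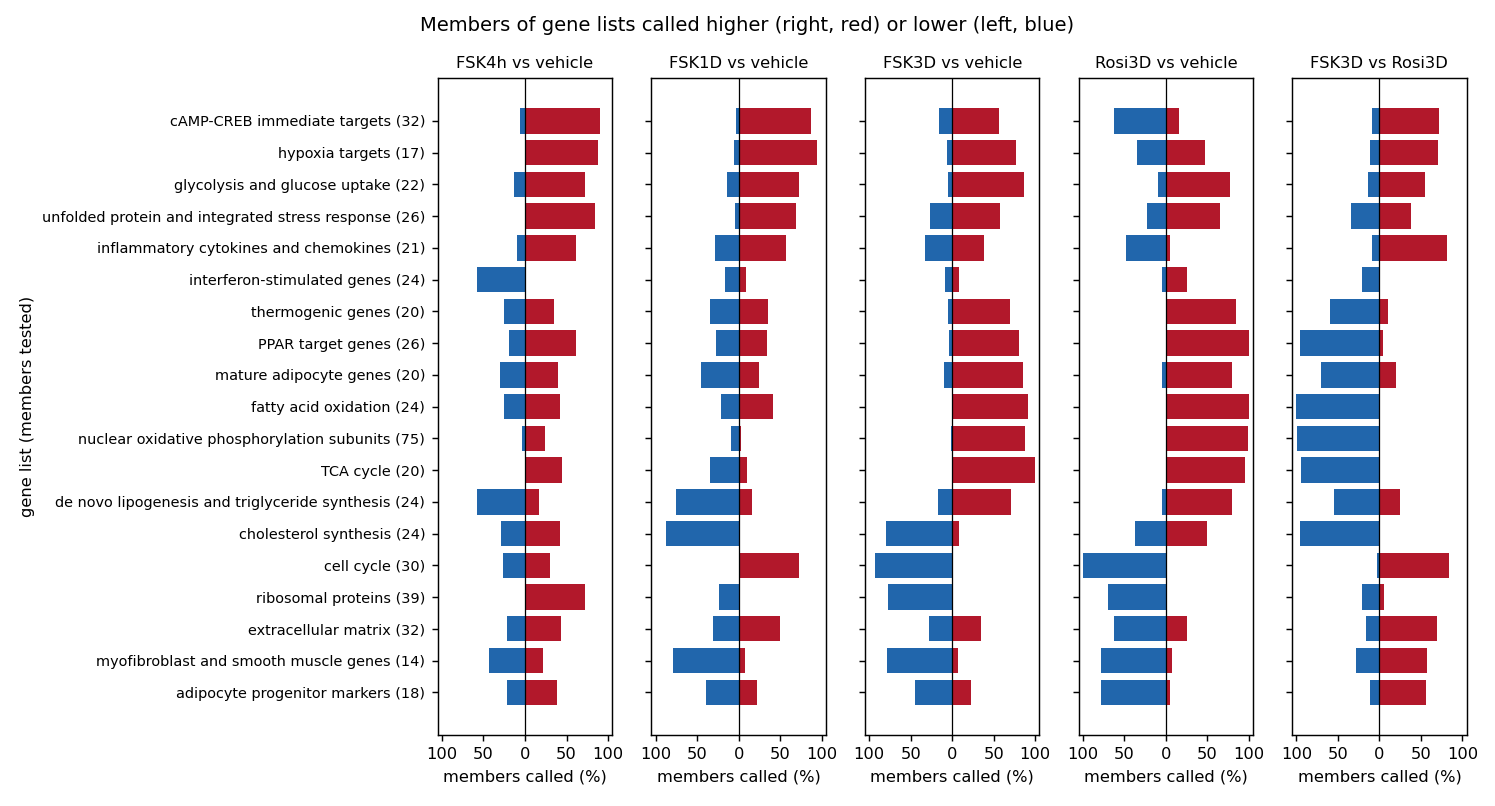
Percent of tested members of 19 gene lists called higher (red, to the right) or lower (blue, to the left) in each of 5 comparisons, with the number tested in parentheses. All 26 PPAR targets were higher in Rosi3D and 29 of 32 cAMP-CREB targets in FSK4h, while in FSK4h with library size alone more members were lower than higher for oxidative phosphorylation, TCA cycle, fatty acid oxidation, mature adipocyte, matrix, cell cycle and cholesterol genes.

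The direct comparison of the 3-day treatments asked whether forskolin and rosiglitazone gave the same state. In FSK3D 3238 genes were higher and 2978 lower than in Rosi3D, 649 and 398 of them by at least 2-fold. Ucp1 was higher in FSK3D, while most of the other thermogenic, mitochondrial and PPAR target genes were higher in Rosi3D. These lists were not called with an estimated correlation, with adjusted p = 0.218 for thermogenic genes, 0.130 for oxidative phosphorylation and 0.130 for PPAR targets. Ucp1 was at 5.25 ± 0.939 CPM in FSK3D against 0.827 ± 0.313 in Rosi3D (2.57 ± 0.24, adjusted p = 7.99e-11). Cidea, at 13.3 ± 2.34 against 40.7 ± 7.53, was lower in FSK3D (-1.59 ± 0.18, adjusted p = 2.48e-06). Lower too were Ppargc1a (-1.047 ± 0.077), Elovl3 (-1.38 ± 0.19) and Adrb3 (-1.85 ± 0.066).

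Thermogenic genes had 2 higher and 12 lower of 20 tested members (2 and 13 adjusted over the list alone), with camera adjusted p = 7.11e-04 (adjusted p = 0.218 with an estimated correlation). PPAR targets had 1 higher and 25 lower of 26 tested members (1 and 25 adjusted over the list alone), a median of -1.38 and camera adjusted p = 2.63e-15 (adjusted p = 0.130 with an estimated correlation). Lower members included Angptl4 at -2.42 ± 0.062, Fabp4 at -1.57 ± 0.12, Pdk4 at -1.40 ± 0.056 and Fgf21 at -2.65 ± 0.29, and Lpl was higher (0.30 ± 0.054). Oxidative phosphorylation had 0 higher and 74 lower of 75 tested members (0 and 74 adjusted over the list alone), with camera adjusted p = 5.58e-25 (adjusted p = 0.130 with an estimated correlation), and fatty acid oxidation 0 higher and 24 lower of 24 tested members (0 and 24 adjusted over the list alone), with camera adjusted p = 7.65e-15 (adjusted p = 0.130 with an estimated correlation). The TCA cycle had 0 higher and 19 lower of 20 tested members (0 and 19 adjusted over the list alone), with camera adjusted p = 4.45e-10 (adjusted p = 0.182 with an estimated correlation). Cholesterol synthesis had 0 higher and 23 lower of 24 tested members (0 and 23 adjusted over the list alone), with camera adjusted p = 7.02e-15 (adjusted p = 0.130 with an estimated correlation), and Insig1 was lower (-1.95 ± 0.053). Mature adipocyte genes had 4 higher and 14 lower of 20 tested members (4 and 14 adjusted over the list alone), with camera adjusted p = 2.34e-04 (adjusted p = 0.456 with an estimated correlation), and Cfd was higher (1.81 ± 0.076). Lipogenesis had 6 higher and 13 lower of 24 tested members (6 and 13 adjusted over the list alone), with camera adjusted p = 0.0172 (adjusted p = 0.620 with an estimated correlation), and Scd1 was higher (0.71 ± 0.052).

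Targets of cAMP-CREB went the other way, with 23 higher and 3 lower of 32 tested members (23 and 3 adjusted over the list alone) and camera adjusted p = 3.22e-07 (adjusted p = 0.119 with an estimated correlation). Pde4d was higher by 1.28 ± 0.051, Pde4b by 2.17 ± 0.075 and Nr4a1 by 1.71 ± 0.099. Inflammatory genes had 17 higher and 2 lower of 21 tested members (17 and 2 adjusted over the list alone), with camera adjusted p = 2.47e-05 (adjusted p = 0.130 with an estimated correlation), and Ccl2 was higher (1.39 ± 0.10). Matrix genes had 22 higher and 5 lower of 32 tested members (22 and 5 adjusted over the list alone), with camera adjusted p = 5.12e-06 (adjusted p = 0.130 with an estimated correlation), and Fbn1 (1.63 ± 0.050) and Fn1 (1.91 ± 0.055) were higher. Cell cycle genes had 25 higher and 1 lower of 30 tested members (25 and 1 adjusted over the list alone), with camera adjusted p = 1.63e-08 (adjusted p = 0.182 with an estimated correlation). Progenitor markers had 10 higher and 2 lower of 18 tested members (11 and 2 adjusted over the list alone), with camera adjusted p = 0.00255 (adjusted p = 0.182 with an estimated correlation), and hypoxia targets 12 higher and 2 lower of 17 tested members (12 and 2 adjusted over the list alone), with camera adjusted p = 1.25e-05 (adjusted p = 0.182 with an estimated correlation). Il1rl1 was at 1167 ± 96.4 CPM against 45.0 ± 4.52 (4.70 ± 0.091), and Tnfrsf9 was higher by 5.65 ± 0.29. Tmem182 (-5.62 ± 0.22), Lrrc39 (-3.84 ± 0.100) and Chrna2 (-3.59 ± 0.17) were lower.

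Genes called higher in both 3-day treatments against vehicle numbered 2564, and 3018 were lower in both. Independent lists of these sizes would share 1069 and 1245 of the 14421 genes, leaving the shared controls out of account. Groups simulated without effects, with a shared set of vehicle libraries that were simulated too, shared at most 1 in each direction over 100 simulations. That is chance with no effect and does not measure what shared controls add among real calls. Genes that were higher in FSK3D and lower in Rosi3D numbered 322, and 175 went the other way (237 and 106 at an adjusted p under 0.01). With 3 vehicle libraries the controls could not be split into sets of at least 2, so part of the excess of shared calls over the independent lists may come from the shared controls. The covariance of fold changes across genes was 0.327, against 0.0253 from the shared simulated vehicle libraries, a difference of 0.302. Pearson's r across genes, which are not independent replicates, was 0.611, against a mean of 0.479 in the simulations. A shared vehicle group alone gave r of 0.439 to 0.514 there, without any effect. The 2 values of r therefore do not show how much of the overlap came from shared controls.

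**Figure D3:**
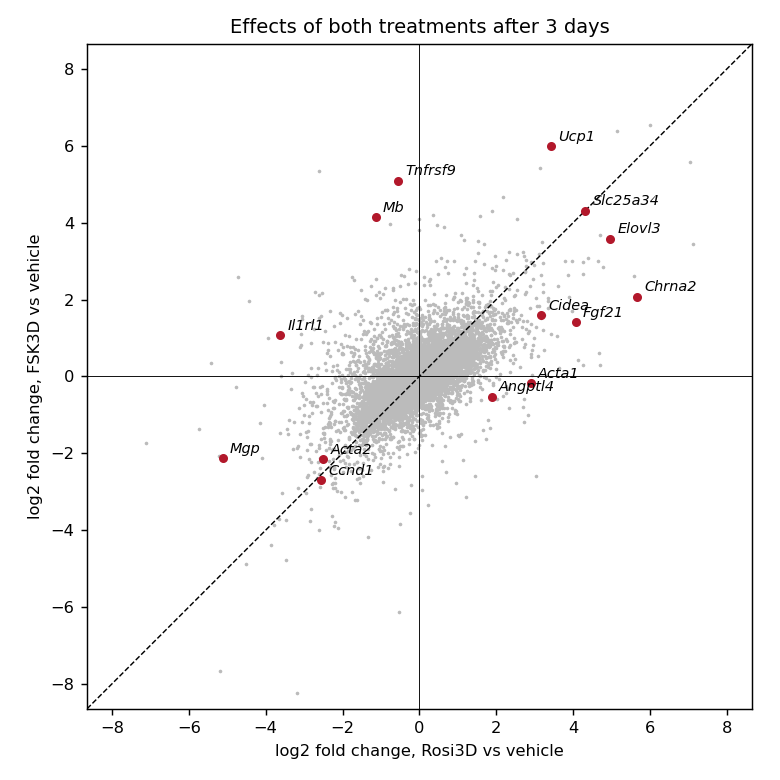
Log2 fold change of 14421 genes in FSK3D against vehicle (vertical) by that in Rosi3D against vehicle (horizontal), 1 grey point per gene, with a dashed line of equal change and named genes in red. Ucp1, Tnfrsf9 and Mb lie above the line, by 2.57, 5.65 and 5.28 in the direct comparison, and Chrna2 and Acta1 lie below it by -3.59 and -3.07.

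Besides the myofibroblast and progenitor lists described above, markers of other cell types covered skeletal muscle, endothelium, nerve or glia and macrophages. Myoglobin (Mb, chromosome 15, 77015487 to 77050670, minus strand), which overlaps other genes, was at 47.5 ± 5.70 CPM in FSK3D against 2.71 ± 1.08 in vehicle (4.15 ± 0.20), and skeletal actin (Acta1, chromosome 8, 123891769 to 123894751, minus strand), a near copy of Acta2, at 29.9 ± 0.738 in Rosi3D against 4.00 ± 0.229 (2.90 ± 0.13). Over the skeletal muscle list 1 higher and 0 lower of 5 tested members (1 and 0 adjusted over the list alone) in FSK3D, with camera adjusted p = 0.867 (adjusted p = 0.888 with an estimated correlation), and 1 higher and 2 lower of 5 tested members (1 and 2 adjusted over the list alone) in Rosi3D, with camera adjusted p = 0.903 (adjusted p = 0.904 with an estimated correlation). The medians of this list were negative (-0.17 and -0.63) while camera pointed higher, and the means were 0.50 and -0.068. Endothelial markers had 0 higher and 2 lower of 5 tested members (0 and 2 adjusted over the list alone) in FSK3D, with camera adjusted p = 0.412 (adjusted p = 0.537 with an estimated correlation), and 1 higher and 4 lower of 5 tested members (1 and 4 adjusted over the list alone) in Rosi3D, with camera adjusted p = 0.207 (adjusted p = 0.392 with an estimated correlation). Eng, which was the most abundant of them, fell to 67.8 ± 0.559 and 56.6 ± 7.13 CPM from 102 ± 2.69. Nerve and glial markers had 2 higher and 4 lower of 9 tested members (2 and 4 adjusted over the list alone) in FSK3D, with camera adjusted p = 0.834 (adjusted p = 0.830 with an estimated correlation), a median of 0.16 and a mean of -0.10, and 2 higher and 3 lower of 9 tested members (2 and 3 adjusted over the list alone) in Rosi3D, with camera adjusted p = 0.739 (adjusted p = 0.763 with an estimated correlation). In Rosi3D Ngfr, which fell at 1 day, rose to 48.2 ± 6.34 CPM (2.11 ± 0.11), while Map2 fell by 0.79 ± 0.12, Tubb3 by 3.02 ± 0.29 and Syt1 by 1.39 ± 0.38 on the log2 scale. Only 4 macrophage markers passed the filter, too few for the list test. Cd14 and Csf1r were higher at 4 h (5.00 ± 1.09 and 2.56 ± 0.174 CPM) and at 1 day (6.09 ± 0.890 and 3.07 ± 0.371) than in vehicle (1.91 ± 0.181 and 0.805 ± 0.136), with adjusted p = 2.27e-07 and 3.74e-06 at 4 h and 1.18e-08 and 5.11e-07 at 1 day. The other tested markers, Cd68 and Cd74, were not called at 4 h (adjusted p = 0.0768 and 0.425) or at 1 day (0.718 and 0.378). In FSK3D Cd14, Csf1r, Cd68 and Cd74 were at 1.63 ± 0.347, 1.66 ± 0.247, 1.91 ± 0.302 and 1.29 ± 0.306 CPM. In Rosi3D they were at 0.840 ± 0.0959, 0.468 ± 0.241, 1.91 ± 0.459 and 1.42 ± 0.346. Cd68 and Cd74 were at 1.75 ± 0.0548 and 0.669 ± 0.243 in vehicle.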

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

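The comparisons between forskolin times were fixed before the data were examined, while all tests on other splits of the libraries were chosen after the results were seen. Each result here was picked out because effects against vehicle were called 1 way at 1 time of forskolin and the other way at another. The difference itself also had to be called, by edgeR or, for lists, by camera with the preset correlation. The p-values of the differences by these tests therefore passed the threshold by selection. Ppargc1a went from 1.22 at 4 h to -0.79 at 1 day, a difference of -2.01 (SE 0.084, adjusted p = 1.15e-17). It then went to 0.64 at 3 days, a difference of 1.43 (SE 0.086, adjusted p = 5.27e-14). Adipoq differed by 1.36 between 3 days (0.22) and 1 day (-1.14), with adjusted p = 5.82e-22. Angptl4 differed by -2.14 between 3 days (-0.53) and 4 h (1.61), with adjusted p = 2.05e-21. Cox8b was at -0.65 at 4 h, -0.60 at 1 day and 1.74 at 3 days, differences of 2.38 (adjusted p = 2.81e-14) and 2.34 (1.59e-13). The 4 h call was lost without FSK4h S4 (-0.47, adjusted p = 0.0530) and the 1 day call without vehicle S2 (-0.47), FSK1D S8 (-0.51) or FSK1D S9 (-0.48).

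Lists were picked out in the same way. Lipogenesis differed by a median of 0.85 between 3 days (0.52) and 1 day (-0.42), with camera adjusted p = 2.12e-10 (adjusted p = 0.252 with an estimated correlation). Cell cycle genes differed by -1.02 between 3 days (-0.83) and 1 day (0.30), with camera adjusted p = 7.43e-21 (adjusted p = 0.115 with an estimated correlation). Ribosomal proteins differed by -0.56 between 3 days (-0.33) and 4 h (0.18, or -0.01 with library size alone), with camera adjusted p = 9.67e-10 (adjusted p = 0.438 with an estimated correlation).

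Other splits of the libraries were set beside the number of calls. For each pair of groups there are 10 splits, too few for a share under 0.05. The real split gave 8514 genes in FSK4h, 5791 in FSK1D, 7628 in FSK3D and 8740 in Rosi3D against vehicle, 6216 in FSK3D against Rosi3D, and 8260, 7358 and 9881 between FSK1D and FSK4h, FSK3D and FSK1D, and FSK3D and FSK4h. In each case it was the 1 split of 10 with as many, and the highest of the other splits was 0 with edgeR's adjusted p, with 162 to 1149 genes at an unadjusted p under 0.05; no other tool was run on the splits. For the time course 1 of 100 splits, the real one with 11754 genes, gave as many, and the highest other gave 5148. That argues only against a random assignment of these libraries to groups. Splits that mix groups add the real differences to the spread within groups, which lowers their calls. Chance differences between cultures are not excluded, since the libraries of a group may be technical. Lists called by camera with the preset correlation were no more frequent in the real split than in the highest other for several comparisons. The real and highest other numbers were 8 and 16 in FSK4h (6 splits with as many), 9 and 14 in FSK1D (8), 18 and 17 in FSK3D (1), 18 and 17 in Rosi3D (1), and 20 and 16 in FSK3D against Rosi3D (1). Between times they were 12 and 16 for FSK1D against FSK4h (3), 13 and 13 for FSK3D against FSK1D (4), and 16 and 15 for FSK3D against FSK4h (1). With 10 splits these shares cannot fall under 0.05 either. Each other split mixes both groups unevenly and keeps part of their real difference, so the lists it calls need not be false.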

How the results depend on the processing

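Halved counts, libraries thinned to the smallest total, for lists RLE factors and abundant genes left out, for overlap and time classes leaving out libraries or abundant genes, and for overlap an adjusted p under 0.01 were chosen after seeing the data; the others were planned. No paired analysis was possible because the columns carry no replicate number of the labels, so the planned fits with a replicate block were not run. Named genes kept their side of the threshold, and their direction where called, in 603 results under DESeq2 (6 calls lost, 1 gained). The same held for 607 under RLE factors (2 lost, 1 gained), 591 under the 1 CPM filter (1 lost) and 3563 with 1 library left out (90 lost, 7 gained). Most named genes were picked from these data for large or clear changes, so they overstate how well calls held. Over all called genes, leaving out 1 library kept fewer calls. The share kept ran from 85.2% (FSK1D against vehicle, without vehicle S1) to 93.9% (FSK3D against FSK4h, without FSK3D S11). Lists kept their side of the threshold, and their direction where called, in 1399 results with 1 library left out (18 calls lost, 23 gained). They did so in 238 under RLE factors (2 lost) and in 228 with library size alone (6 lost, 6 gained). An uncalled gene or list counted as kept whatever its direction. With the estimated correlation 110 list calls were lost and 4 held. Lep in Rosi3D was lost under DESeq2 (adjusted p = 0.149). Pparg in FSK4h reversed to -0.15 with library size alone (adjusted p = 0.0476), where the median of all genes moved by -0.19. Depth limits genes near the floor of 3 counts.

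With library size alone, FSK4h had 2519 genes higher and 6708 lower, FSK1D against FSK4h 2709 lower, and the early classes 1818 higher and 4895 lower. At an adjusted p under 0.01, 106 genes were lower in FSK3D and higher in Rosi3D. With each library left out, calls ran from 3938 to 4024 higher and 3921 to 4001 lower in FSK4h, 2647 to 2744 and 2428 to 2578 in FSK1D, 3467 to 3685 and 3355 to 3611 in FSK3D, 3921 to 4112 and 4115 to 4318 in Rosi3D, and 2841 to 3076 and 2604 to 2938 in FSK3D against Rosi3D. Lists called lower ran from 1 to 2 in FSK4h (2 without vehicle S1 or FSK4h S5) and from 3 to 6 in FSK1D (3 without vehicle S2, 6 without FSK1D S8).

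Camera with an estimated correlation called 1 list higher and 0 lower in FSK4h, 1 and 1 in FSK1D, 0 and 1 in FSK3D against FSK4h, and 0 and 0 in FSK3D, Rosi3D, FSK3D against Rosi3D, FSK1D against FSK4h and FSK3D against FSK1D. At an unadjusted p under 0.05 the same test had 3 and 0 in FSK4h, 4 and 2 in FSK1D, 3 and 2 in FSK3D, 5 and 2 in Rosi3D, 4 and 4 in FSK3D against Rosi3D, 0 and 3 in FSK1D against FSK4h, 1 and 2 in FSK3D against FSK1D, and 0 and 3 in FSK3D against FSK4h. Fry called 17 higher and 6 lower in FSK4h, 13 and 9 in FSK1D, 18 and 7 in FSK3D, 16 and 12 in Rosi3D, 13 and 10 in FSK3D against Rosi3D, 3 and 18 in FSK1D against FSK4h, 16 and 8 in FSK3D against FSK1D, and 13 and 12 in FSK3D against FSK4h. The thinned libraries gave 2 lists lower in FSK4h. Fry reversed white adipocyte markers (adjusted p = 0.0228) and lipolysis (0.0326) in FSK4h, chromatin enzymes in Rosi3D (0.00962), and circadian (0.00147) and secreted factors (1.13e-04) in FSK3D against FSK4h. Fry compares no list with other genes; for the other changes the cause was not tested.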

Other observations

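The tests of explanations for the 3 patterns here were chosen after the patterns were seen, and all but the thinning test for the interferon genes after the values they measure were seen. Members of further lists changed. Of the list results given here, camera with the preset correlation called circadian genes and secreted factors in FSK3D and interferon-stimulated genes in Rosi3D, and all 3 calls were lost with an estimated correlation. Circadian clock genes in FSK4h had 10 higher and 6 lower of 19 tested members (10 and 6 adjusted over the list alone), with camera adjusted p = 0.306 (adjusted p = 0.667 with an estimated correlation). Per3 fell (-2.05 ± 0.065) and Nfil3 rose (2.38 ± 0.096). In FSK3D the list had 10 higher and 2 lower of 19 tested members (11 and 3 adjusted over the list alone), with camera adjusted p = 0.00955 (adjusted p = 0.156 with an estimated correlation). Creatine and calcium cycling had 6 higher and 2 lower of 11 tested members (6 and 2 adjusted over the list alone) in FSK3D, with camera adjusted p = 0.0752 (adjusted p = 0.156 with an estimated correlation). Alkaline phosphatase, Alpl, was high at every forskolin time (2.23 ± 0.056, 2.36 ± 0.056 and 2.03 ± 0.056) and fell in Rosi3D (-1.04 ± 0.061). The calcium pump Atp2a3 rose in Rosi3D (3.61 ± 0.12).

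Secreted factors had 14 higher and 6 lower of 24 tested members (14 and 7 adjusted over the list alone) in FSK3D, with camera adjusted p = 0.0326 (adjusted p = 0.268 with an estimated correlation), and 0.0568 without the 20 most abundant genes. Chromatin enzymes moved both ways, with 10 higher and 8 lower of 31 tested members (11 and 8 adjusted over the list alone) in FSK3D and camera adjusted p = 0.867 (adjusted p = 0.951 with an estimated correlation). The demethylase Kdm3a rose at 4 h (1.16 ± 0.050), and Dnmt1 fell at 3 days (-1.048 ± 0.048). White adipocyte markers had 9 higher and 5 lower of 15 tested members (9 and 5 adjusted over the list alone) in FSK3D, with camera adjusted p = 0.0569 (adjusted p = 0.156 with an estimated correlation), and the vitamin D receptor Vdr rose at 4 h (3.15 ± 0.091). Beige markers had 5 higher and 1 lower of 9 tested members (5 and 2 adjusted over the list alone) in Rosi3D, with camera adjusted p = 0.0752 (adjusted p = 0.283 with an estimated correlation). Abundant noncoding RNAs had 2 higher and 4 lower of 9 tested members (2 and 4 adjusted over the list alone) in FSK3D, with camera adjusted p = 0.453 (adjusted p = 0.505 with an estimated correlation). Their median was 0.038, while their mean (-0.21) and camera pointed lower. In the matrix list at 1 day 16 rose and 10 fell of 32 tested members (16 and 12 adjusted over the list alone), with camera adjusted p = 0.0873 (adjusted p = 0.701 with an estimated correlation), and Col3a1 rose (1.94 ± 0.056). Interferon-stimulated genes had 6 higher and 1 lower of 24 tested members (5 and 1 adjusted over the list alone) in Rosi3D, with camera adjusted p = 0.0440 (adjusted p = 0.732 with an estimated correlation). That preset call was lost without vehicle S2 (0.129), vehicle S3 (0.100), Rosi3D S13 (0.0833) or Rosi3D S14 (0.131), and under RLE factors (0.0520), a 1 CPM filter (0.0613) and halved counts (0.0601).

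Ucp1 was higher in FSK3D than in Rosi3D while 12 of 20 thermogenic genes were lower. Counting noise is argued against by the ratio of 5.76, from 182 and 46 halved counts, with a lower 95% bound of 4.20. A difference in depth is argued against by libraries thinned to the smallest total, in which the log2 fold change was 2.42. Raised cAMP signalling after 3 days of forskolin may contribute, but the test was undecided, with an adjusted p of 0.119 for the cAMP-CREB targets with an estimated correlation. That test does not ask whether Ucp1 followed these targets. Against vehicle the targets were called with an estimated correlation at 4 h and at 1 day, where Ucp1 was at 8.42 and 1.15 CPM. They were not so called at 3 days, where Ucp1 was at 5.25 CPM.

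The overlap of both 3-day treatments was weighed against 3 technical or cellular explanations. The shared vehicle libraries alone are argued against by the covariance of 0.327, above the highest of 100 simulations (0.0285). The simulations redrew the vehicle libraries from the fitted spread, and so do not cover a shift common to all real vehicle libraries. A smaller share of undifferentiated cells as the whole cause stays open in both treatments. In FSK3D 4 progenitor markers were higher and in Rosi3D 1 was, but more were lower in each. Pdgfra was already at 373 CPM in FSK4h and Ly6a at 431 in FSK1D, against 209 and 121 in vehicle. Their level at 3 days therefore cannot stand for the share of progenitor cells. Longer time in culture than the vehicle libraries could also play a part, since their harvest time is not given. Of 5582 genes changed in the same direction by both, 37.0% were called that way in FSK1D and 15.3% the other way. In FSK4h 35.8% were called that way and 31.9% the other way. These shares decide nothing.

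The mean log2 CPM of interferon-stimulated genes varied between libraries of 1 group. In FSK1D this mean was 4.36, 5.06 and 3.73, with Oasl2 at 25.9, 47.7 and 14.4 CPM and Ifit3 at 9.42, 23.7 and 6.43. Whether all members varied together, or more than other lists, was not tested. Thinning to the smallest total left the within-group SD of the list's mean log2 CPM at 0.418 against 0.424, a ratio of 0.984. These values were already scaled to library size. Thinning therefore argues only against an effect of depth on low counts, and cannot exclude other effects of library size. The Rn45s share stays a possible explanation, as Pearson's r of the within-group deviations over 15 libraries was -0.107 (interval -0.665 to 0.526, permutation p = 0.765), Spearman's rho -0.143 (permutation p = 0.683), and r -0.200 without the 2 farthest libraries. With library total as the other of 2 relations, r was -0.113 (permutation p = 0.655, rho -0.00357 with p = 0.995, r -0.0376 without the 2 farthest), both Benjamini-Hochberg values were 0.765, and no biological explanation was tested.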
